A study of Mus musculus with 2 samples.

How the data were processed

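The series holds 2 RNA sequencing libraries of mouse TRAMP prostate tumours, 1 control and 1 with Foxf1 overexpression, each made from the pooled RNA of 3 tumours per the series' design text. RNA was isolated with the Qiagen RNeasy Mini kit, and a core facility prepared the libraries, per the labels' protocols. The groups were taken from the sample titles. The aligner, the quantifier and its version, the read length, the strand setting and the genome build are not given in the sources used here.

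The authors deposited 1 table per library with FPKM values, fragments per kilobase of transcript scaled to the mapped fragments of the library, for 28107 RefSeq transcripts, per the file headers. The same tables give the coverage of each transcript, a signal of mean read depth per base that the authors' quantifier estimated, per the file headers. The layout, with a status for each estimate, is that of Cufflinks-type isoform tables. Within each table FPKM divided by coverage was 1 constant, to within 0.00093%, and this constant gives the mapped bases behind the library, 941 Mb for the control and 873 Mb for the Foxf1 library. Transcripts of the tables took up 76.0% and 77.7% of those bases.

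No read counts were used here, so depth was estimated. In low transcripts, coverage times length gathers at multiples of the bases that 1 read is worth. The lowest peak was placed at its median between 30 and 65 bases in transcripts of at least 2000 nucleotides, which was 45.4 bases for the control and 47.7 for the Foxf1 library, or about 20.7 M and 18.3 M reads. From the reads so estimated, a 95% interval of each ratio of FPKM was computed as an exact conditional (Clopper-Pearson) interval. It rests on that estimate, ignores the splitting of reads among transcripts, and covers neither the spread between tumours nor that between libraries. The smallest number of estimated reads in the lower library among the 12 highest and 12 lowest genes was 40.8. Genes with at least 1 FPKM numbered 11767 and 11792 in the control and the Foxf1 library, and 5071 and 5152 were listed at 0.

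Transcript FPKM values were summed per gene symbol. The 28 genes with a failed estimate in either library (42 and 41 transcripts) were left out, which left 22044 genes. The log2 ratio was that of FPKM + 1, Foxf1 library over control, and genes with a mean of the 2 libraries of at least 5 FPKM (the floor) entered all counts and lists. Lengths are those deposited per transcript, combined per gene by level. Folds in the text are ratios of FPKM without a pseudocount. With 1 library per group no test between conditions exists, so genes were counted by a size of 2-fold on the log2(FPKM + 1) scale and no p-value was computed.

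The genes named in the text follow a rule fixed before the data were examined. They are Foxf1, the 12 genes with the highest and the 12 with the lowest log2 ratio over the floor with an ordinary symbol (no clone names, predicted genes, small RNAs or immune receptor segments), and from each list the 2 to 4 members over the floor with the largest absolute log2 ratio. All other genes were chosen after their values were seen, also where the text does not mark them so. The result of 1 gene is not reported here. The 48 gene lists, of pathways and of cell types that a tumour under the skin could hold, were also fixed before, and 648 of their 661 entries matched a gene of the tables. For each list the median log2 ratio over members, with its order-statistic 95% interval (the range for fewer than 6 members), was set against 10000 random lists of the same size. These were drawn from the 7908 ordinary genes over the floor and matched on mean expression in 20 bins. Lists with fewer than 3 members over the floor have a median only. Percentiles describe these libraries, since genes of a list are not replicates.

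The deposited coordinates reach 152509964 on chromosome 7, beyond the highest gene end of GRCm38.p6 on that chromosome, 145324059, so the files use another build. Coordinates are printed as deposited, with starts counted from 1 instead of 0, since in 3284 transcripts the deposited end minus start equals the transcript length. GC content came from GENCODE transcript sequences of that reference, matched by RefSeq identifier, for 8405 genes (98.9% of those over the floor).

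Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, scaling to a median ratio of 0 or to equal upper quartiles, floors of 1 and 10 FPKM and no floor, sizes of 1.5-fold and 3-fold, ordinary symbols only, transcripts in place of genes, means in place of medians, and random lists without matching. Added after seeing the data were the removal of the trend of the log2 ratio with log length (lowess, fraction 0.3), genes with a transcript of at least 300 nucleotides, and random lists matched on expression and length (5 by 8 bins) or on length and GC content (8 by 8 bins). The median ratio differed from 0 by 0.03 and the upper quartiles by 0.05 on the log2 scale. Of the tests of explanations, 4 were run and then dropped or replaced: muscle spread against counting error, set before its result was seen, and 3 chosen after, the copy number of chromosome 9 judged from its nearest neighbours alone, a shuffle test of the highest genes, which had been picked for lying together, and a shuffle test of windows of genes over a level, which left out the highest of them.

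The procedure was tested on simulated data for the comparison of the Foxf1 library with the control, with reads drawn for 7908 genes at the observed levels and depths. All 50 genes planted at 3-fold and all 50 at 6-fold passed the 2-fold size, none of the 50 at 1.3-fold and of the 50 at 1.5-fold did, and 0 of 7708 unchanged genes did. The intervals held the planted ratio for 95.3% of genes. Of 200 lists without a planted change, 13 lay outside the middle 95%, and a list of 15 genes planted 1.5-fold higher stood at percentile 100. These simulated lists held no trend with length or GC content and no genes that move together. Only genes with ordinary symbols were simulated. The simulation therefore does not cover such trends, nor clone-named genes and small RNAs. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.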

Results

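Gene expression was measured by RNA sequencing in mouse prostate tumours with and without forced expression of Foxf1, a forkhead transcription factor of the mesenchyme. TRAMP tumours come from a transgenic C57BL/6 model in which a viral oncogene drives prostate cancer, and here they grew under the skin of mice of the same strain for 3 weeks. RNA of 3 control tumours was pooled into 1 library, and RNA of 3 Foxf1-overexpressing tumours was pooled into another. The comparison asks which genes accompany the tumour progression that the series title attributes to Foxf1. Each library lists FPKM values for 28107 transcripts of 22072 genes. The values correspond to 941 Mb of mapped bases in the control and 873 Mb in the Foxf1 library, or about 20.7 M and 18.3 M reads by estimate. With 1 library per group there is no replicate check and no p-value, so every difference below describes these 2 libraries. The 95% intervals cover counting error only, and leave out the spread between tumours and between libraries. They treat reads as independent, although reads without molecular identifiers are not independent molecules, so they may be too narrow.

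Foxf1 was higher in the library labelled as overexpressing it. Its level, listed under the older symbol Foxf1a, was 0.183 FPKM in the control and 1.12 FPKM in the Foxf1 library, a 6.11-fold difference (95% interval 2.07 to 24.3). The gene lies on chromosome 8 from 123608374 to 123610779 in the coordinates of the files, whose genome build is not given in the sources used here. About 4.02 and 21.7 reads stood behind these values, and the gene ranked 11648th of 22044 genes in the Foxf1 library. On the log2(FPKM + 1) scale, which understates the change of low genes, the difference was 0.84. Among other forkhead genes, Foxf2 was at 9.90 and 11.7 FPKM (log2 ratio 0.23), Foxa2 at 5.49 and 4.79 FPKM (−0.16) and Foxm1 at 29.5 and 32.2 FPKM (0.12). The median of the 5 forkhead genes over the expression floor was 0.07, at percentile 57.2 of random lists, and −0.13 after removal of the length trend described below.

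The remaining transcriptome was similar in the 2 libraries. Of 8496 genes with a mean of at least 5 FPKM, 98.0% lay within 1.5-fold, and the levels correlated across genes with a Pearson r of 0.98. The median log2 ratio was 0.03, with the 10th percentile at −0.23 and the 90th at 0.30. Genes at least 2-fold apart numbered 15 higher and 34 lower in the Foxf1 library, and the counting interval excluded a ratio of 1 for 15 and 33 of them. With clone-named genes and small RNAs left out, 7 were higher and 27 lower.

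Among the genes higher in the Foxf1 library were secreted growth factors, a matrix protein and matrix-degrading enzymes. Ptn, which encodes the heparin-binding growth factor pleiotrophin, was at 7.42 FPKM in the control and 27.6 FPKM in the Foxf1 library, 3.72-fold higher (3.27 to 4.23). Postn, encoding the matricellular protein periostin, was at 74.7 and 154 FPKM (2.07-fold, 2.0 to 2.15). The collagenase gene Mmp13 was at 19.8 and 44.4 FPKM (2.24-fold, 2.08 to 2.41), and Mmp10, encoding stromelysin 2, at 6.04 and 12.6 FPKM (2.09-fold, 1.76 to 2.48). Hgf, which encodes the ligand of the receptor tyrosine kinase Met, was 2.21-fold higher (1.86 to 2.64), and Il1rn, encoding the interleukin 1 receptor antagonist, 2.18-fold higher (1.84 to 2.60). Lnpep, a membrane aminopeptidase gene, had a log2 ratio of 1.18, the nuclear receptor coactivator gene Ncoa3 1.08, the tankyrase gene Tnks 0.98 and Plac8 0.95. The nuclear long noncoding RNA Malat1 was at 42.3 and 86.7 FPKM (log2 ratio 1.02). Zbed6 was at 2.48 and 9.10 FPKM (1.54), but it lies inside the span of Zc3h11a, listed at 42.4 and 48.2 FPKM, so its reads are uncertain. Folds are plain ratios of FPKM. On the log2(FPKM + 1) scale Tnks, Il1rn, Hgf, Plac8 and Mmp10 stayed under 2-fold. After removal of the length trend described below, Postn was at 0.94, Ncoa3 at 0.86, Malat1 at 0.80 and Tnks at 0.79, all under 2-fold. Ptn was then at 1.80, Zbed6 at 1.38, Mmp13 at 1.06 and Lnpep at 1.02.

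Genes of skeletal muscle and fat were prominent among the lower genes. Of the 27 lower genes with ordinary symbols, 12 were on the skeletal muscle list fixed before the data were examined and 2 on the adipocyte list. Cfd, which encodes the adipokine adipsin, was at 33.7 FPKM in the control and 4.24 FPKM in the Foxf1 library, 7.95-fold lower (6.22 to 10.3). Krt8, encoding a keratin of simple epithelia, was at 26.9 and 4.36 FPKM, 6.16-fold lower (5.17 to 7.39). Tcap, which encodes the sarcomere protein telethonin, was 5.71-fold lower (4.38 to 7.56), the muscle glycogen phosphorylase gene Pygm 5.47-fold lower (4.53 to 6.65) and the myosin light chain gene Myl1 4.0-fold lower (3.44 to 4.48). The other genes among the 12 lowest were the muscle list members Mb, Atp2a1, Ckm, Tnnt3, Pvalb, Tnnc2 and Tnni2, with log2 ratios from −2.47 to −1.95.

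**Figure D1:**
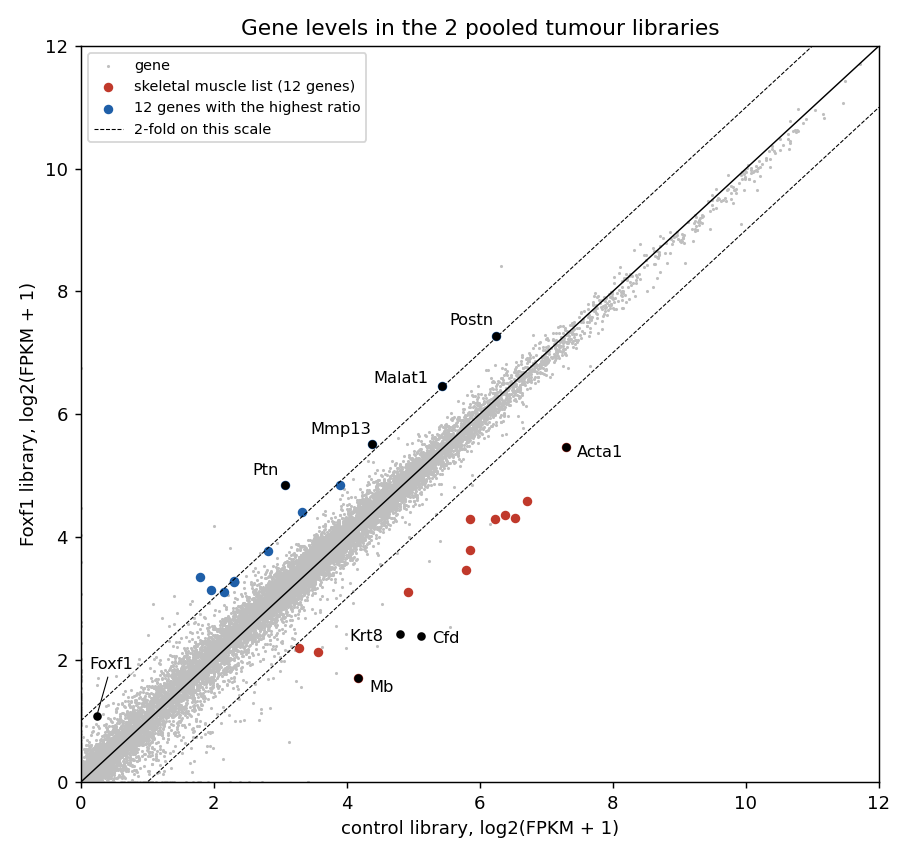
Each grey point is a gene at its log2(FPKM + 1) in the control library (horizontal) and the Foxf1 library (vertical); blue points are the 12 highest ratios, red points the 12 skeletal muscle genes, black points named genes, and dashed lines mark 2-fold on this scale. The skeletal muscle genes, Cfd and Krt8 lie below the lower dashed line, while most genes lie close to the diagonal.

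All 12 members over the floor, of 16 on the skeletal muscle list, were at least 2-fold lower in the Foxf1 library. The list's median log2 ratio was −1.98 (95% interval over members −2.23 to −1.56), at percentile 0 among 10000 random lists matched on mean expression. Mb, encoding the oxygen store myoglobin, was at 17.0 and 2.26 FPKM. Atp2a1, encoding the calcium pump of fast fibres, was 5.42-fold lower (4.98 to 5.90) from a control level of 54.1 FPKM, and the muscle creatine kinase gene Ckm at 91.0 and 18.7 FPKM. The 3 adipocyte genes over the floor had a median of −1.63 (range −2.73 to −0.80). Besides Cfd they were Car3, a carbonic anhydrase gene abundant in fat and muscle, at 36.7 and 11.2 FPKM, and the fatty acid binding protein gene Fabp4 at 48.0 and 27.1 FPKM. The erythroid list had 2 members over the floor with a median of −0.83. They were Beta-s at 58.2 and 31.0 FPKM and Hba-a1 at 10.5 and 5.74 FPKM, globin genes whose near-identical copies can share reads.

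The fibrillar matrix list was higher in median in the Foxf1 library, with members going both ways. The 15 members over the floor had a median log2 ratio of 0.35 (−0.05 to 0.66), above every random list matched on expression, and 11 of the 15 were above 0. Eln, which encodes elastin, was at 16.0 and 29.6 FPKM (0.85), the small proteoglycan genes Dcn and Lum were at 26.4 and 47.7 FPKM (0.83) and at 20 and 36.4 FPKM (0.83), and the thrombospondin gene Thbs2 was at 0.66. The most abundant collagen of the list, Col1a1, chosen after its values were seen, was at 557 and 558 FPKM. The collagen genes Col1a2, Col3a1, Col5a1 and Col5a2, also chosen after, were at 0.12, 0.35, −0.06 and 0.33. Metalloproteinase and remodelling genes had a median of 0.18 over 16 members (−0.06 to 0.42), at percentile 99.98. Besides Mmp13 and Mmp10, the macrophage elastase gene Mmp12 was at 5.18 and 10.3 FPKM (0.87), whereas the urokinase receptor gene Plaur was at −0.44. Longer transcripts were generally higher in the Foxf1 library, and both lists stayed high against random lists matched on expression and length (percentiles 100 and 99.7). After removal of the length trend the medians were 0.18 for the fibrillar matrix list and 0.09 for the metalloproteinase list. Members above 0 then numbered 9 of 15 and 9 of 16.

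The basement membrane list had a median of 0.18 over 9 genes (0.02 to 0.27) and stood at percentile 98.95. Col4a1, encoding a chain of type IV collagen, was at 57.8 and 78.5 FPKM (0.43) and the nidogen gene Nid1 at 50.5 and 61.0 FPKM (0.27). These transcripts are long, and against random lists of matched expression and length the percentile was 47.0. After removal of the length trend the median was −0.03, with 4 of 9 members above 0. Integrin and focal adhesion genes had a median of 0.11 over 11 members, at percentile 97.2. The laminin receptor gene Itga6 was at 4.35 and 7.19 FPKM (0.62) and Itgav at 0.34. With length matched this list stood at percentile 52.1, and its median was −0.02 after removal of the length trend.

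Chemokine and cytokine genes were higher, whereas antigen presentation genes of MHC class II were lower. The 15 inflammatory genes had a median of 0.32 (0.12 to 0.40), above every random list, and 12 of the 15 were above 0. Cxcl14 was at 7.50 and 12 FPKM (0.61), the neutrophil chemoattractant gene Cxcl1 at 30.5 and 45.1 FPKM (0.55) and the monocyte chemoattractant gene Ccl2 at 57.6 and 81.9 FPKM (0.50), while the cytokine gene Lif was at 6.92 and 4.61 FPKM (−0.50). All 6 MHC class II genes over the floor were below 0, with a median of −0.44 (−0.63 to −0.11) at percentile 0. Cd74, encoding the invariant chain, was at 544 and 351 FPKM (−0.63) and H2-Eb1 at 160 and 107 FPKM (−0.58). Type I interferon response genes had a median of −0.11 over 16 members (−0.33 to 0.09), at percentile 0.65, with the ubiquitin-like modifier gene Isg15 at 51.5 and 36.5 FPKM (−0.48) and Oasl1 at −0.43. Genes induced by interferon gamma, including MHC class I, had a median of −0.06 over 14 members at percentile 17.1, with the chemokine gene Cxcl10 at −0.39.

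Macrophage and monocyte markers had a median of 0.08 over 15 members (−0.09 to 0.22), at percentile 96.2 with expression matched and 99.3 with expression and length matched. The mannose receptor gene Mrc1 was at 14.5 and 26.5 FPKM (0.83) and the integrin gene Itgam at 24.8 and 31.2 FPKM (0.32). Fibroblast markers over the floor were lower. Their median was −0.21 over 6 members (−0.46 to 0.07) at percentile 0.78, with Lrrc15 at 12.6 and 8.91 FPKM (−0.46) and the gelsolin gene Gsn at −0.32. Under the floor, and chosen after their values were seen, the fibroblast genes Pdgfra (1.51 and 3.92 FPKM) and Fap (1.15 and 3.02 FPKM) were higher in the Foxf1 library. At a floor of 1 FPKM the fibroblast median was −0.04 over 10 members (−0.32 to 0.90). Smooth muscle and pericyte markers had a median of −0.18 over 6 members (−1.02 to 0.49) at percentile 2.29, with the intermediate filament gene Des, shared with skeletal muscle, at 26 and 12.3 FPKM (−1.02) and Mcam at 0.49. The direction of that list was lost at a floor of 1 FPKM, where its median was 0.01. Endothelial markers had a median of −0.08 over 7 members at percentile 5.52, with the fenestral diaphragm gene Plvap at −0.51 and the cadherin gene Cdh5 at 0.33.

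Genes of the ERK5 pathway, a mitogen-activated kinase route distinct from ERK1/2, were slightly higher. The 11 members over the floor had a median of 0.18 (−0.19 to 0.48) at percentile 98.33, and at 97.70 with length matched. Map3k2, which encodes an upstream kinase of the pathway, was at 8.78 and 13.4 FPKM (0.56), the transcription factor gene Mef2a at 7.93 and 11.5 FPKM (0.48) and the kinase gene Wnk1 at 32.4 and 40.4 FPKM (0.31), while the autophagy receptor gene Sqstm1 was at −0.28. After removal of the length trend the list's median was 0.04, with 7 of the 11 members above 0. Map3k2 was then at 0.29, Mef2a at 0.40, Wnk1 at 0.04 and Sqstm1 at −0.24. Mapk7, which encodes ERK5 itself and was chosen after its values were seen, was at 15.2 and 14.6 FPKM. The ERK1/2 kinase cascade had a median of 0.03 over 11 genes at percentile 68.5, which turned to −0.01 with upper quartiles set equal, with Braf at 0.33 and Map2k1 at −0.27. Feedback and immediate early genes of ERK signalling had a median of 0.05 over 18 genes at percentile 69.3, and at 98.7 with length and GC content matched. The ERK inhibitor gene Spred1 was at 12.9 and 19.9 FPKM (0.59), Ier3 at 79.0 and 57.5 FPKM (−0.45) and Jun at 0.44.

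Proliferation genes were slightly higher, with a median of 0.13 over 31 members (0.06 to 0.24) at percentile 99.5, and 99.7 with length matched. The mitotic kinesin gene Kif11 was at 12.6 and 18.7 FPKM (0.54), the proliferation marker gene Mki67 at 7.98 and 12 FPKM (0.53) and the topoisomerase gene Top2a at 35.3 and 49.3 FPKM (0.47). In total 23 of the 31 were above 0 and none was 2-fold apart. With upper quartiles set equal the median was 0.08. After removal of the length trend it was 0.11, with 28 of the 31 members above 0. Kif11, Mki67 and Top2a, which have long transcripts, were then at 0.39, 0.27 and 0.31.

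Most genes of the epithelial list were under the floor. Of its 16 genes 4 passed the floor, with a median of −0.38 (range −2.38 to 0.16) at percentile 0.09, and with no floor the median over all 16 was −0.14. Besides Krt8, Krt19 was at 54.9 and 41.3 FPKM (−0.40) and Krt7 at 16.5 and 12.6 FPKM (−0.37). Krt18, the partner of Krt8 in filaments, was under the floor at 4.07 and 2.59 FPKM. Epcam, Esrp1 and Esrp2, also under it, were lower in the Foxf1 library too, with counting intervals that excluded equal levels. Cldn3, Cldn7, Ocln, Dsp and Ovol1 had lower values as well, but their intervals included equal levels. Dsp rested on about 3.72 and 2.65 reads. The cadherin gene Cdh1 (0.387 and 0.632 FPKM), the claudin gene Cldn4 (0.0941 and 0.371 FPKM, about 3.53 and 12.3 reads) and Grhl2 were under the floor and higher. The interval of Grhl2 included equal levels. These genes under the floor were chosen after their values were seen. On the list of TRAMP tumour cell and prostate epithelium markers, 2 genes passed the floor with a median of −1.47, Krt8 and the tetraspanin gene Tspan8 (103 and 69.2 FPKM). Mesenchymal genes had a median of −0.11 over 14 members (−0.29 to 0.38) at percentile 8.18, and at 0.39 with length matched, and their mean was 0.06. Besides Postn, the repressor gene Zeb1 was at 17.2 and 23.1 FPKM (0.41) and the tenascin gene Tnc at 0.38, whereas the smooth muscle actin gene Acta2 was at 293 and 226 FPKM (−0.37).

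Glycolytic and hypoxia-inducible genes were lower, with 19 of 21 below 0. The list's median was −0.19 (−0.26 to −0.13) at percentile 0.03. Car9, a carbonic anhydrase gene induced by low oxygen, was at 15.5 and 8.49 FPKM (−0.80), the aldolase gene Aldoa at 703 and 519 FPKM (−0.44) and the enolase gene Eno1 at 300.3 and 233 FPKM (−0.36). Gapdh, with many pseudogenes that can share its reads, was at −0.39. Genes of skeletal muscle, a tissue rich in glycolytic enzymes such as aldolase, were lower in the same library. All 12 muscle list members over the floor were at least 2-fold lower, and a link between the lists was not tested. Heat shock genes were higher, with a median of 0.21 over 10 genes (0.11 to 0.62) at percentile 99.97. Hspa1b was at 8.40 and 13.8 FPKM and its near-identical copy Hspa1a at 8.62 and 13.7 FPKM, so the split of reads between them is uncertain. The chaperone gene Hsph1 was at 25.5 and 34.9 FPKM (0.43).

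Other metabolic and stress lists lay within the middle 95% of random lists matched on expression, 3 of them not under every other matching. Cholesterol synthesis genes had a median of −0.04 over 16 members at percentile 11.2, with Fdps at −0.46 and Mvd at −0.34. The percentile was 1.25 with expression and length matched and 0.66 with length and GC content matched. After removal of the length trend the median was −0.16, with 4 of 16 members above 0. Nuclear genes of oxidative phosphorylation had a median of −0.12 over 17 members at percentile 10.4, and at 0.71 without matching, with Atp5o at −0.35 and Cox6c at −0.28. After removal of the length trend their median was −0.01. Ribosomal protein genes, which have many pseudogenes, had a median of −0.12 over 18 members at percentile 34.1, and at 0.25 without matching. Their median was 0.02 after removal of the length trend. The unfolded protein response had a median of −0.05 over 14 members at percentile 33.7, with the stress factor gene Ddit3 at −0.41. Targets of p53 had a median of −0.05 over 10 members at percentile 12.4, which was 0.02 at a floor of 1 FPKM and 0.08 with no floor, with Bax at −0.35 and Btg2 at 0.27.

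Signalling lists were similar. Genes of TGF-beta signalling had a median of 0.11 over 15 members at percentile 89.8, with the activin subunit gene Inhba at 0.52 and Id3 at 0.46. Angiogenesis genes had a median of 0.01 over 9 members at percentile 46.8, which turned to −0.02 with the median ratio set to 0 and to −0.04 with upper quartiles set equal. It was 0.09 at a floor of 1 FPKM and 0.11 after removal of the length trend, and the mean was 0.23. That list held Hgf and the gene of its receptor, Met, at 20.6 and 31.7 FPKM (0.60). The 4 Notch pathway genes over the floor had a median of 0.04 at percentile 39.4, which turned to −0.01 with upper quartiles set equal and to −0.05 after removal of the length trend, with the ligand gene Jag1 at 0.50. Hedgehog genes had a median of 0.29 over 2 members, Sufu (0.44) and Smo (0.14). Androgen targets had a median of −0.40 over 2 members, Fkbp5 at 32.9 and 22.0 FPKM (−0.56) and Ndrg1 (−0.25).

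Markers of other cell types seldom passed the floor. The neuroendocrine list had 2 such genes with a median of −0.27, Ncam1 and Eno2, and the dendritic cell list 2 with a median of −0.14, Ccr7 and Itgax. Single genes passed for prostate basal cells (Dst, 0.31), lymphatic endothelium (Pdpn, −0.25) and B and plasma cells (Sdc1, −0.44). No member passed for Wnt targets, neutrophils, T cells, natural killer cells, mast cells, skin keratinocytes or Schwann cells, and no entry of the mitochondrially encoded list was matched. Of the 31 lists with at least 3 members over the floor, 15 lay outside the middle 95% of random lists, 7 high and 8 low. Of these, 6 high and 8 low also did so with lists matched on expression and length and on length and GC content. Lists of independently drawn genes would give 1.55 outside. Members of a fixed list can move together, so that number does not measure chance between 2 single libraries.

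**Figure D2:**
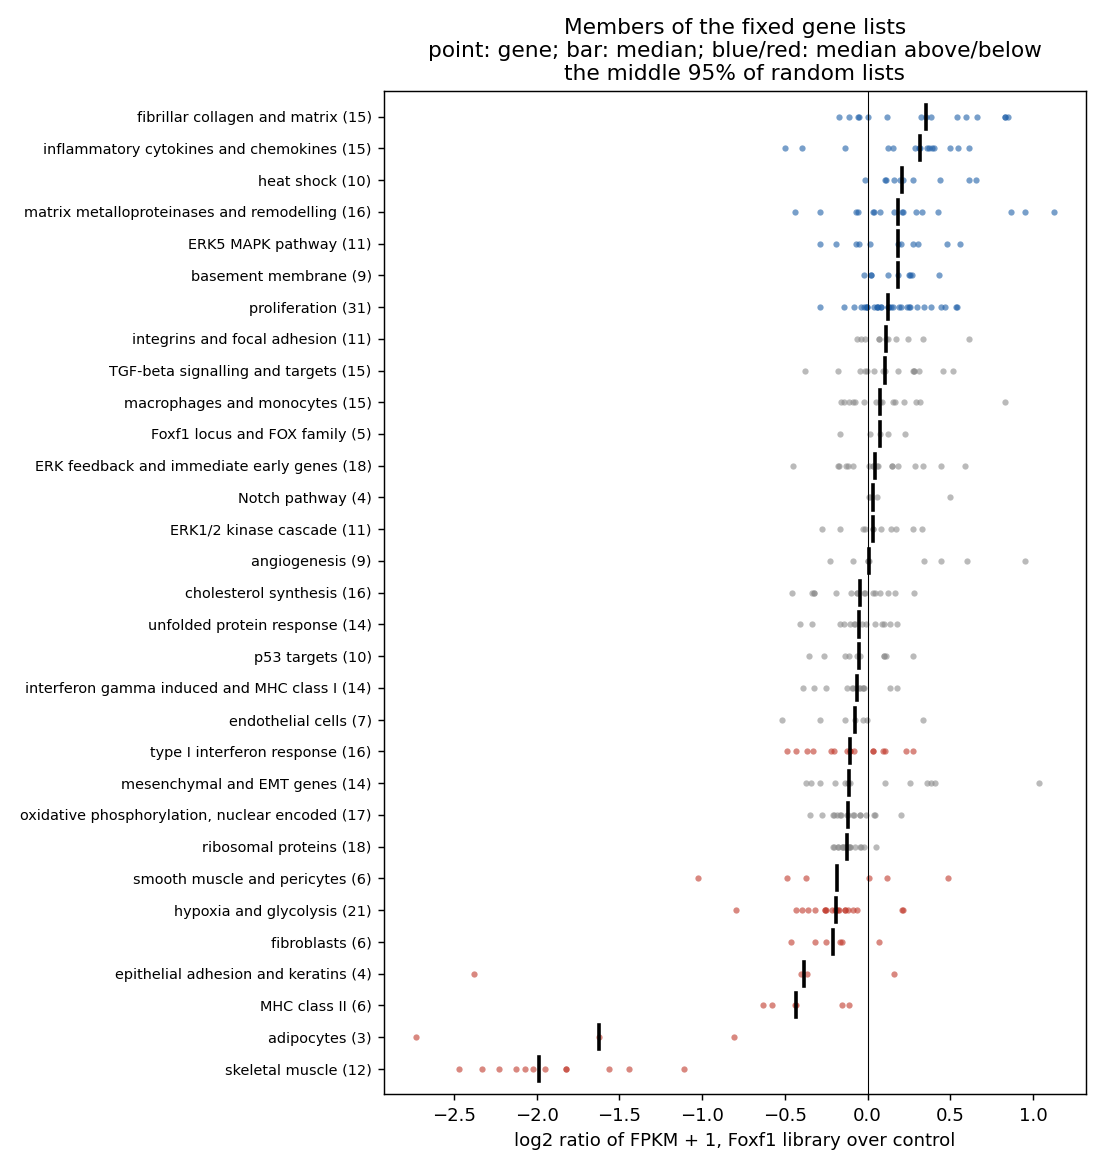
Each point is a gene over the floor at its log2 ratio of FPKM + 1 (Foxf1 library over control), each bar a list's median, with the number of genes in brackets; blue and red mark medians above and below the middle 95% of random lists matched on expression. The skeletal muscle list has a median of −1.98 and the fibrillar matrix list 0.35, and medians within 0.05 of 0 for angiogenesis, Notch and ERK1/2 genes turned negative under another scaling.

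Transcript length moved with the ratio between the libraries. Across the 8496 genes, which are not independent replicates, Spearman's rho between length and log2 ratio was 0.56. The median log2 ratio was −0.15 in the 10% of genes with the shortest transcripts and 0.21 in the 10% with the longest. The median length was 1219 nucleotides for the skeletal muscle genes and 4698 for the fibrillar matrix genes. With the length trend removed, the skeletal muscle median was −1.90, the fibrillar matrix median 0.18 and the chemokine and cytokine median 0.28. The GC content of the transcripts also moved with the ratio (rho −0.43 across 8405 genes).

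**Figure D3:**
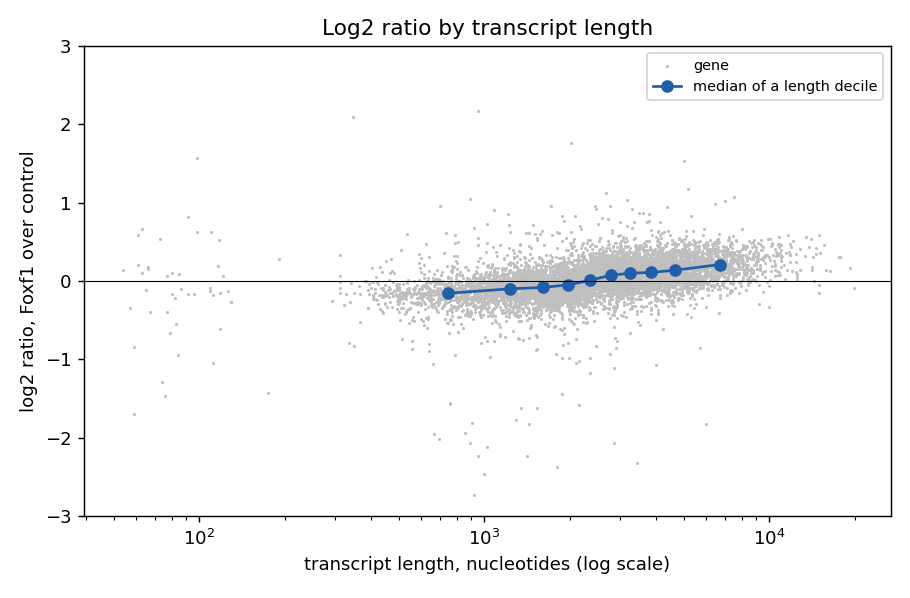
Each grey point is a gene over the floor at its transcript length in nucleotides (log axis) and its log2 ratio of FPKM + 1 (Foxf1 library over control); blue points join the medians of 10 groups of equal size by length, and a few small nucleolar RNA genes lie beyond the vertical axis. The medians run from −0.15 for the shortest transcripts to 0.21 for the longest.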

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

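The removal of the length trend, the limit to transcripts of at least 300 nucleotides and random lists matched on length were chosen after the data were seen; the other alternatives were planned. The Foxf1 log2 ratio of 0.84 (0.39 to 1.11) was 1.24 with a pseudocount of 0.5 and 2.10 with 0.1, because the gene is near 0 FPKM and a pseudocount shrinks low genes. The 15 higher and 34 lower genes became 42 and 79 at a floor of 1 FPKM, 9 and 21 at a floor of 10, 58 and 98 with no floor, 84 and 90 at 1.5-fold, 7 and 21 at 3-fold, and 59 and 62 with transcripts in place of genes; with ordinary symbols only, 7 were higher. Other floors, sizes and symbols change by construction which genes count; for transcripts the cause was not tested. For the 15 lists outside the middle 95%, 133 of 135 medians under 9 settings kept their sign and stayed within their interval. These intervals over members are wide, so the count is a weak check. With the length trend removed the ERK5 median of 0.18 became 0.04 and the fibrillar matrix median of 0.35 became 0.18. The fibroblast median of −0.21 became −0.04 at a floor of 1 FPKM, and all 3 stayed inside. The smooth muscle median became 0.0075 at a floor of 1, where more members enter, and the basement membrane median became −0.028 with the length trend removed. The basement membrane percentile of 98.95 was 97.0 without matching, 47.0 with expression and length matched and 97.3 with length and GC content matched; these transcripts are long. Scalings for counts were not run, since no counts were used here, and with 1 library per group no library could be left out. No paired analysis was possible because each group has 1 library. Depth limits genes near 0 FPKM most: Foxf1 rests on about 4.02 reads in the control.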

Other observations

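Tests of counting noise, and of GC content, expression level and chromosome for the length trend, were set before their results were seen; all other tests in this part were chosen after, including the one now used for the make-up of muscle, which replaces a test set before. Several genes outside the lists, and list members under the floor, were also apart. All genes in this paragraph were chosen after their values were seen. Haptoglobin (Hp), a plasma protein gene also active in fat, was at 22.1 FPKM in the control and 6.51 FPKM in the Foxf1 library, and Ndrg2 was at 8.46 and 2.15 FPKM. Pgam2, Myoz1 and Cox6a2, known from striated muscle but absent from the muscle list, were at 14.9 and 3.54, 8.96 and 1.93, and 8.34 and 3.48 FPKM. Adipocyte genes under the floor were lower too, with adiponectin (Adipoq) at 3.42 and 0.297 FPKM, Cidec at 2.13 and 0.242 FPKM and resistin (Retn) at 2.72 and 0.510 FPKM. The inflammatory caspase genes Casp1 (99.7 and 53.8 FPKM) and Casp4 (586 and 454 FPKM) were lower, and the growth factor gene Pdgfd was higher (67.4 and 105 FPKM). The lysyl oxidase gene Lox, whose product crosslinks collagen and elastin, was at 2.80 and 6.58 FPKM. It is a member of the metalloproteinase and remodelling list under the floor. The small nucleolar RNA genes Snord1a, Snord58b, Snord49a and Snord37 were listed at 0 in the control and at 11.0, 15.4, 21.1 and 107 FPKM in the Foxf1 library. Their transcripts are shorter than 300 nucleotides.

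Counting noise of independent reads does not account for the 49 genes at least 2-fold apart as a set. Reads drawn at equal rates for both libraries gave a mean of 2.25 such genes over 100 draws (0 to 7). Reads that are not independent would add noise that these draws leave out. Single genes with few reads are not settled by the draws, such as Snora31 with about 16.5 and 5.98 reads (ratio interval 0.13 to 1.10). Spread between tumours was not measured and stays open.

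Longer transcripts were higher in the Foxf1 library. The tables argue against GC content as the whole cause, since rho within each of 10 GC groups was at least 0.42 (to 0.62), and against expression level, with rho of at least 0.42 (to 0.59) within each of 10 groups by mean FPKM. A different fragment length setting in the quantifier would act mostly on short transcripts, yet rho was 0.25 (0.22 to 0.28) among 3385 genes over 3000 nucleotides. The trend held on each of the 19 autosomes, with rho from 0.52 to 0.68, but any cause that acts by transcript length would give this. A difference in library preparation or RNA integrity may be the cause, and these values cannot decide it. A cellular difference that follows transcript length would give the same values and was not tested, and the design, with 1 library per group, confounds it with preparation.

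Skeletal muscle genes were lower in the Foxf1 library. The length trend does not account for it, as the median was −1.90 with the trend removed. A lower share of all non-tumour cells would lower macrophage, endothelial and fibroblast markers as much, but the lowest bound of their median intervals was −0.51, against an upper bound of −1.56 for muscle. Muscle of the same make-up in different amounts cannot be told apart: the test set before, of the members' spread (SD 0.41, from 2.48-fold to 7.52-fold lower) against counting error (0.10), met its bound for exclusion but is dropped, since genes of single libraries vary by more than counting error (median SD 0.21 in random lists matched on expression), and among those lists the muscle SD stood at percentile 92.2. As a hypothesis, different amounts of muscle and fat of the implantation site in the pools, with varied fibre types or some expression in other cells, could underlie the pattern; 0 of the 16 muscle list genes are on another list, Acta1 was at 156 and 43.3 FPKM, and an effect of Foxf1 was not tested apart from it.

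The fibrillar matrix and metalloproteinase lists were higher in median in the Foxf1 library. Against random lists matched on expression and length they stood at percentiles 100 and 99.7, which argues against the length trend as the whole cause, although the trend removal lowered the medians from 0.35 to 0.18 and from 0.18 to 0.09. More copies of the chromosome 9 block that holds Mmp3, Mmp10, Mmp12 and Mmp13 would raise its neighbours too. The 12 neighbours over the floor were not raised together. They ran from −0.88 (Casp1) to 0.63 (Pdgfd), with Dcun1d5 at −0.07 and Tmem123 at 0.20. Pdgfd and Dync2h1 (0.54) nevertheless lay above Mmp3, the lowest of the 4 metalloproteinases at 0.42, so more copies cannot be told apart. More fibroblasts in the Foxf1 pool cannot be told apart from a change within cells either. The fibroblast markers over the floor reached at most 0.067, below the matrix median, but at a floor of 1 FPKM, with Pdgfra and Fap included, the interval of their median was −0.32 to 0.90, and 1 of the 11 markers is shared with another list; an effect of Foxf1 on matrix genes stays open as well.

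Among the highest genes by mean level over both libraries were Dcun1d5 (2812 FPKM, ranked 2nd of all genes), Tmem123 (1885 FPKM, 7th) and Yap1 (1692 FPKM, 10th), which lie on chromosome 9 from 7184566 to 8004596. They are not an unbroken run: metalloproteinase genes with means as low as 0.0858 FPKM (Mmp1a) lie between Dcun1d5 and Tmem123. The apoptosis inhibitor genes Birc2 (447 FPKM, 135th) and Birc3 (39.9 FPKM) lie between Tmem123 and Yap1. Nearby, Casp12 (609 FPKM, 96th), Casp4 (520 FPKM, 113th) and 9230110C19Rik (443 FPKM, 136th) were also high, whereas Ddi1 (0.503 FPKM) was low. The log2 ratios of Dcun1d5, Tmem123, Birc2, Birc3 and Yap1 ran from −0.10 for Birc3 to 0.20 for Tmem123. The genes in this paragraph were chosen after their values were seen, and no explanation of these levels was tested.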
